A study of Mus musculus with 12 samples.

How the data were processed

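Total RNA of CD8+ T cells from C57BL/6 mouse splenocytes was sequenced in 12 libraries, 3 for each of 4 treatments: IL-2, IL-2 with 80%TCM, IL-12 and IL-12 with 80%TCM. Per the labels, libraries were made with a directional NEBNext Ultra II total RNA kit, and the strand setting of the counting is not given in the sources used here. The protocol text on extraction speaks of bortezomib-treated livers, which no sample label names. Gene counts were made by the authors after alignment with STAR 2.7.7a, and the processing notes also name edgeR without a version or its role, per the submitters' processing notes. The second deposited kind of file holds a signal per gene and library that the authors computed from the counts: each deposited value equals the count divided by 1 constant per library, as counts per 1e+06 counts (CPM) on library sizes scaled by TMM. The notes name a human genome build although the gene identifiers are those of mouse, and no coordinates were used here.

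From the count table, libraries were scaled by TMM, low genes were removed with filterByExpr (minimum count 10, minimum total 15), and 15897 of 55487 genes were tested. The model had 1 mean per group over all 12 libraries in edgeR 4.0.16 (quasi-likelihood F test, common biological coefficient of variation 0.104), with p-values adjusted by Benjamini-Hochberg over all genes tested in each contrast and a threshold of 0.05. The 5 contrasts were TCM within IL-2, TCM within IL-12, IL-12 against IL-2 without TCM and with TCM, and the difference of the TCM effect between the cytokines. Printed levels are CPM on TMM-scaled library sizes, errors of levels are SD over 3 libraries, and errors of log2 fold changes are standard errors taken from the fold change and the F statistic. Symbols came from the name table given with the files for 55141 gene identifiers, and 346 had none, with 0.029 to 0.053% of the counts. The 10 genes with the most counts took 5.02 to 5.49% of each library.

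Gene groups were 49 lists of 1002 symbols fixed before the data were examined, of which 962 matched the table and 40 did not, and the 45 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on voom weights, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists. A list member counts as higher or lower by its genome-wide adjusted p, and counts adjusted over the list alone use the members' p-values only. Named genes follow a rule written before the files were opened. It takes the 8 highest and 8 lowest log2 fold changes per contrast among called genes with a mean of at least 10 CPM in the higher group and no overlap between groups, leaving out unnamed gene models. For each called list it takes the 3 members with the smallest p in the list's direction, and it adds 26 anchor genes of T cell biology. For the difference of effects it takes the 6 highest and 6 lowest genes with 10 CPM in the highest group. Not every anchor is printed in every comparison, some genes that the rule names are not reported here, and other genes are said to have been chosen after their values were seen.

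The alternatives planned were DESeq2 size factors or upper-quartile scaling, no filter on low counts or a mean of at least 5 CPM, DESeq2 1.42.0, limma on the deposited signal as log2(CPM + 1), with 0.1 or 5 added instead and at least 1 CPM in 3 libraries, only the 2 groups compared, the replicate number as a block, each library left out, an absolute log2 fold change of at least 1, and for lists an estimated correlation and members of no other list. Leaving out replicate 3 of both IL-2 groups and a block within the IL-2 groups only were added after seeing the data. Whether equal replicate numbers mark matched samples was checked from the residuals of each library. Between IL-2 and IL-2 with TCM the same-number correlations were 0.28, 0.25 and 0.57, all above 0.1. Those of replicates 1 and 2 with each other were as high, at 0.3 and 0.27, and those of replicate 3 with either were -0.36 to -0.41, so that the data tell replicate 3 apart but do not tell replicates 1 and 2 apart. Between the other groups they lay from -0.04 to 0.07. The chi-square per degree of freedom between replicates, over genes with at least 20 reads, was 2.4 to 5.51 and 28.5 to 45.4 for pairs with replicate 3 of an IL-2 group, where counting error alone gives 1.

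The scripts were tested on simulated data drawn from the real means and library sizes, with 50 genes changed at each fold. For TCM within IL-2, edgeR recovered 25, 37, 43 and 50 genes changed 1.5-, 2-, 4- and 8-fold and called 12 unchanged genes. For the difference of effects it recovered 17, 33, 37 and 49 and called 12 unchanged genes. The comparison without simulated change gave 0 calls in edgeR, and log2 fold changes of the changed and unchanged comparisons had a correlation of 0. A 30-gene list moved 1.2-fold was called by camera at adjusted p = 4.8e-39 and 0 other lists were. Genes were drawn independently of each other, so this simulation cannot judge the preset correlation of 0.01. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.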

Results

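CD8+ T cells are the T cells that kill infected or malignant cells. Messenger RNA levels were measured by bulk RNA sequencing in CD8+ T cells prepared from C57BL/6 mouse splenocytes and kept with IL-2 or IL-12. IL-2 is a growth and survival cytokine of T cells, and IL-12 is a cytokine that signals through STAT4 and induces interferon gamma. Each cytokine was given with or without 80%TCM, a term that the labels do not spell out, while the title of the series speaks of tumor-like conditions. This gave 4 groups of 3 libraries. In units of 1e+06, between 19.5 and 26 counts fell on genes in each library, except in replicates 1 and 2 of the IL-12 group without TCM, which held 49.6 and 42.3 and carry less counting error. Of 55487 gene identifiers, 32285 had at least 1 count and 15897 passed the filter on low counts. Levels are given as counts per 1e+06 counts (CPM), mean ± SD over n = 3 libraries. The labels do not say whether the libraries of a group came from separate animals or cultures, so that the p-values measure only the spread between these samples, which may be technical.

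The cytokine set the libraries apart most. The first principal component held 56.8% of the variance and separated the IL-2 from the IL-12 libraries. The second held 17.3% and separated the libraries with TCM from those without within each cytokine, but narrowly within IL-2. There replicates 1 to 3 lay at 28.9, 24.8 and -0.3 without TCM and at -6.3, -7.4 and -38.4 with TCM. Within IL-2 this component thus also held a shift of replicate 3. Replicate 3 of IL-2 and replicate 3 of IL-2 with TCM stood apart from the other libraries of their groups. Pkm, which encodes the last enzyme of glycolysis, was at 4030 CPM in replicate 3 of IL-2 against 1140 and 1190 CPM in replicates 1 and 2, and at 3970 CPM against 1150 and 1090 CPM with TCM. Vegfa, a vascular growth factor induced by low oxygen, was at 32.9 CPM against 2.42 and 3.26 CPM, and at 57.2 CPM against 7.03 and 7.12 CPM with TCM. Of 23 glycolysis genes, 22 were higher in both of these libraries than in the other replicates, with median log2 shifts of 1.18 and 1.25. Of 26 hypoxia response genes, 23 were higher in both, with shifts of 1.15 and 1.30. Counts of called genes that these libraries moved by over 1.5 times, and some list counts, are also given without them, a choice made after seeing the data.

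**Figure D1:**
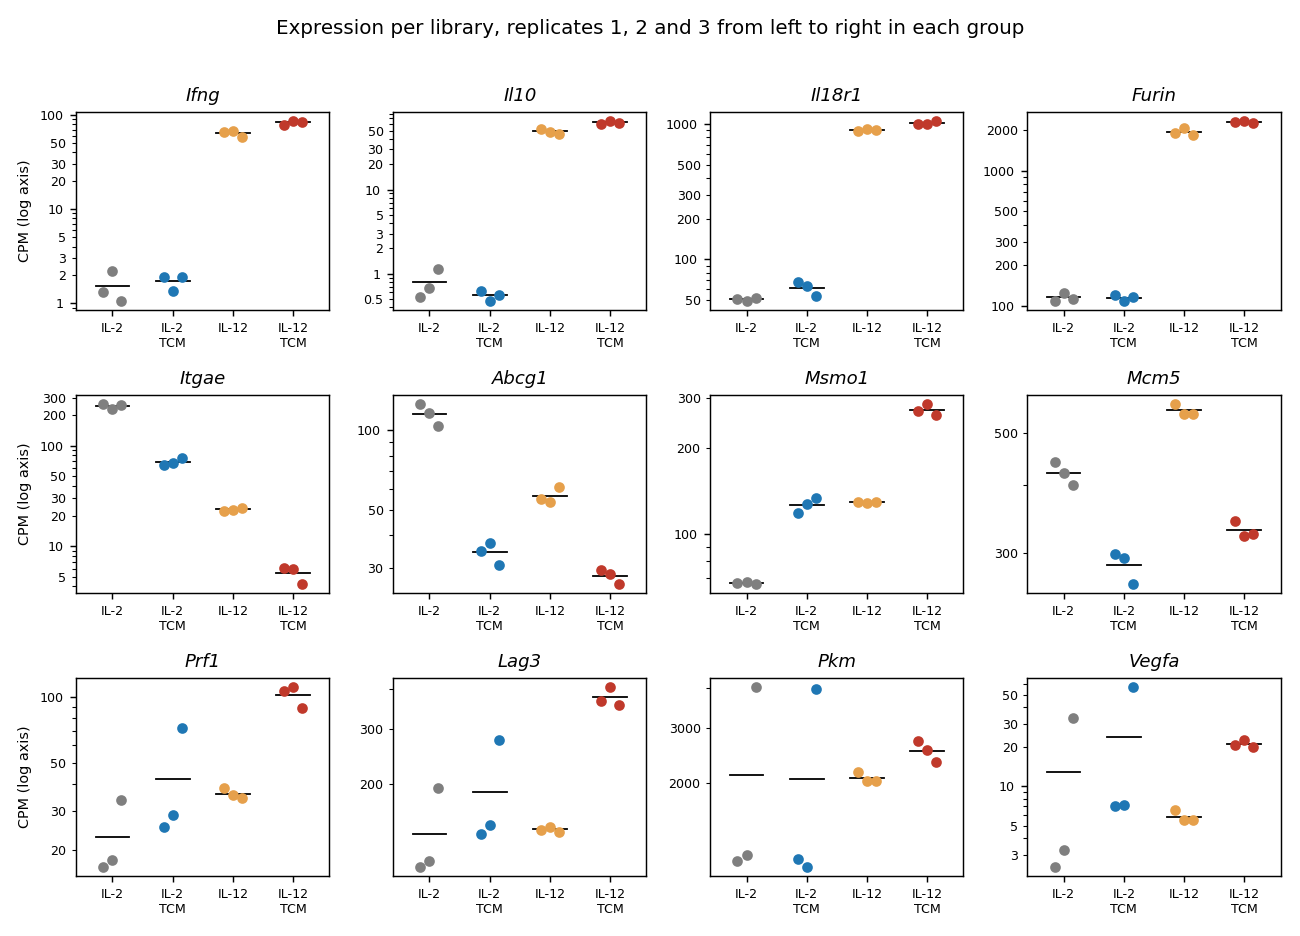
Levels of 12 genes in each library, in CPM on a log axis, with one point per replicate (1 to 3 from left to right) and a black line at the group mean. Furin, Il18r1, Ifng and Il10 were higher in the IL-12 libraries, Itgae and Abcg1 were lower with TCM, and Pkm and Vegfa stood out in replicate 3 of both IL-2 groups.

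The first comparison asked how TCM changed cells kept with IL-2. Abca1 and Abcg1, transporters that export cholesterol from cells, fell with TCM, Abca1 (ENSMUSG00000015243) from 28.0 ± 2.41 to 6.64 ± 0.404 CPM (n = 3; 4.22-fold) and Abcg1 from 115 ± 11.3 to 34.4 ± 3.35 CPM (3.35-fold). Itgae (ENSMUSG00000005947), the integrin CD103 by which T cells bind epithelium, fell from 249 ± 14.2 to 68.9 ± 6.39 CPM, and Rap1gap2, which inactivates the adhesion GTPase Rap1, fell from 11.5 ± 1.66 to 1.78 ± 0.433 CPM. Emp1, Fgl2 and Gpr34 fell 2.98-, 3.74- and 2.87-fold. Bst1, an ectoenzyme that cleaves NAD, rose from 12.7 ± 1.29 to 37.1 ± 2.99 CPM, and Tg and Mirt1 rose 2.54- and 2.43-fold. Ctla4, an inhibitory receptor, rose from 246 ± 6.83 to 366 ± 35.1 CPM, and Stat4 rose 1.30-fold. Adjusted p-values from edgeR for these genes lay between 9.8e-08 for Abca1 and 0.00025 for Ctla4. Tcf7, Tbx21, Eomes, Tnf, Ifng and Pdcd1, genes of T cell differentiation and function, were not called (adjusted p = 0.65, 0.67, 0.74, 0.97, 0.75 and 0.55).

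Of 25 genes of cholesterol synthesis, 24 rose and 1 fell with TCM in IL-2, with the same counts adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, rose from 193 ± 25 to 371 ± 22.7 CPM and Msmo1 from 67.1 ± 0.415 to 126 ± 8.05 CPM. The gene that fell was Ebp (log2 fold change -0.19), named here after its values were seen. The median log2 fold change was 0.57, and the list was called by camera (adjusted p = 6.6e-26, and adjusted p = 0.032 with an estimated correlation). It was the only list of this comparison that kept its call with an estimated correlation.

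Genes of cell division were lower with TCM in IL-2. In the DNA replication list 25 of 30 genes fell (26 adjusted over the list alone), among them Mcm5 from 421 ± 20.7 to 285 ± 19 CPM, Cdc6 from 65.7 ± 6.29 to 41.2 ± 4.32 CPM and Uhrf1 from 429 ± 10.9 to 318 ± 11 CPM. Its median was -0.36 (adjusted p = 4.3e-20, and adjusted p = 0.22 with an estimated correlation). In the mitosis list 17 of 28 genes fell (22 adjusted over the list alone), such as Top2a, Kif20a and Kif23, with a median of -0.27 (adjusted p = 1.2e-11, and adjusted p = 0.38 with an estimated correlation). Of 27 genes of MYC activity and ribosome biogenesis, 4 fell (8 adjusted over the list alone), among them the transferrin receptor gene Tfrc, from 396 ± 35 to 256 ± 28.8 CPM. That list was called at adjusted p = 0.0016 (adjusted p = 0.66 with an estimated correlation) and not called without replicate 2 of IL-2 (adjusted p = 0.12). Without replicate 3 of both IL-2 groups 18 of its genes were lower (adjusted p = 9.4e-11, and adjusted p = 0.24 with an estimated correlation).

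Some TGF-beta response genes and genes of trafficking and adhesion were also lower with TCM in IL-2. Of 21 TGF-beta response genes, 9 fell and 2 rose (10 and 4 adjusted over the list alone). Itgae is a member of both lists, and Ldlrad4 and Ski, both inhibitors of TGF-beta signalling, fell from 20.2 ± 4.33 to 7.39 ± 1.31 CPM and from 134 ± 3.30 to 88.5 ± 8.41 CPM. The TGF-beta list had a median of -0.21 (adjusted p = 0.0018, and adjusted p = 0.074 with an estimated correlation). Of 25 trafficking genes, 8 fell and 1 rose (10 and 3 adjusted over the list alone), including the chemokine receptor gene Cxcr6, from 45.5 ± 6.58 to 23.4 ± 1.75 CPM, and Itgb1, from 318 ± 7.58 to 231 ± 3.19 CPM. That list was called at adjusted p = 0.02 (adjusted p = 0.22 with an estimated correlation), and not without the genes it shares with other lists (adjusted p = 0.11). Of 15 effector cytokine and chemokine genes, 3 fell (4 adjusted over the list alone), among them Ccl5 from 57.5 ± 6.24 to 35.6 ± 5.86 CPM. The adjusted p of the list was 0.046 (adjusted p = 0.38 with an estimated correlation), and the call was lost without replicate 1 or replicate 2 of IL-2 (0.087 and 0.13).

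Transcripts typical of other cell types moved as well. Of 7 platelet and megakaryocyte genes, 6 fell with TCM in IL-2 (7 adjusted over the list alone). Ppbp and Pf4, chemokines of platelets, fell from 32.8 ± 4.61 to 10.9 ± 2.36 CPM and from 32.1 ± 5.66 to 11.9 ± 2.72 CPM, and Itga2b, the platelet integrin CD41, fell from 42.5 ± 3.44 to 23.4 ± 2.09 CPM. The median was -1.11 (adjusted p = 1.0e-08, and adjusted p = 0.074 with an estimated correlation). Of 9 CD4 T cell and regulatory T cell genes, 4 rose (4 adjusted over the list alone), including Cd4 from 1.21 ± 0.0506 to 3.81 ± 0.934 CPM beside Cd8a at 912 ± 86 and 1070 ± 53.7 CPM. That call (adjusted p = 0.046, and adjusted p = 0.22 with an estimated correlation) was lost with upper-quartile scaling (adjusted p = 0.051). It was also lost, with values of 0.054 to 0.079, on leaving out any library except replicates 1 and 3 of IL-2 with TCM, replicate 3 of IL-12 and replicate 2 of IL-12 with TCM.

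With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2313 genes were called for TCM in IL-2, 1070 higher and 1243 lower, of which 161 and 180 changed at least 2-fold. The count was 587 with only these 2 groups in the fit, 3936 without replicate 3 of both IL-2 groups, 1292 without replicate 1 and 1432 without replicate 2 of IL-2, and 4442 with the replicate number as a block within the IL-2 groups. Genes not called in the fit without a block and called with it include Prf1, which encodes perforin (22.8 ± 9.53 and 41.9 ± 25.8 CPM, adjusted p = 0.1, with the block 6.3e-07), the inhibitory receptor gene Lag3 (139 ± 47.8 and 188 ± 77.1 CPM, adjusted p = 0.26, with the block 3.2e-06) and the granzyme gene Gzmb (1070 ± 230 and 1370 ± 446 CPM, adjusted p = 0.27, with the block 0.0066). Over all alternatives their adjusted p-values ran from 3.6e-23 to 0.43 for Prf1, from 2.2e-08 to 0.84 for Lag3 and from 5.9e-06 to 0.82 for Gzmb. The lowest were those without the filter on low counts, a fit not run on the simulated data, so how far they hold is not known. Prf1 and Lag3 were also called without replicate 3 of both IL-2 groups (1.8e-05 and 2.7e-05). The block within the IL-2 groups was chosen after seeing the data. The planned block over all libraries called none of Prf1, Lag3, Gzmb, Havcr2 and Il7r for TCM in IL-2. With the block within the IL-2 groups, Havcr2 and Il7r were called as well (0.012 and 0.028, against 0.43 and 0.35). So were the lists of CD8 T cell identity (0.035), the IL-12 and STAT4 axis (0.041), IL-2 and STAT5 targets (0.0053), costimulation (0.04), glycolysis (2e-05), hypoxia response (0.00068), the unfolded protein response (0.031) and NRF2 targets (0.044), each lost with that block and an estimated correlation (adjusted p = 0.24 to 0.61 with an estimated correlation). For the cytotoxic granule, IL-12 and STAT4, and fatty acid oxidation lists, none of them called without the block, the median, the mean and the test differed in sign.

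The next comparison asked how TCM changed cells kept with IL-12. Rap1gap2 fell from 10.3 ± 0.565 to 0.448 ± 0.172 CPM (n = 3; 22.7-fold), Itgae from 23.2 ± 0.852 to 5.43 ± 1.02 CPM (4.27-fold) and Tmem154 from 18.3 ± 0.974 to 3.98 ± 0.374 CPM (4.59-fold). Cxcl10, a chemokine that attracts T cells, Thbs1, an adhesive matrix protein, and Uchl1, a deubiquitinase, fell 3.69-, 3.10- and 3.42-fold. Trim66 (ENSMUSG00000031026) rose from 17.8 ± 0.906 to 101 ± 6.55 CPM (5.67-fold), Lama5, a laminin chain, from 7.17 ± 0.902 to 38.4 ± 4.28 CPM and Neb, a giant protein of muscle thin filaments, from 55.4 ± 2.62 to 198 ± 25.4 CPM. Ffar2, a receptor for short-chain fatty acids, rose from 1.96 ± 0.140 to 10 ± 0.519 CPM.

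Single genes of killing and of receptors rose with TCM in IL-12, while their lists were not called. Of 19 cytotoxic granule genes, 5 were higher and 6 lower (7 and 6 adjusted over the list alone, adjusted p = 0.62), and of 27 inhibitory receptor genes 7 were higher and 2 lower (7 and 4 adjusted over the list alone, adjusted p = 0.32). Prf1 rose from 36.1 ± 1.97 to 102 ± 11.5 CPM (2.82-fold), Gzmb from 475 ± 87.1 to 1070 ± 84.8 CPM (2.26-fold) and Lag3 from 143 ± 2.44 to 377 ± 26.4 CPM (2.63-fold). Il2ra, the high-affinity IL-2 receptor chain, rose 1.26-fold, Il7r 1.44-fold, Ctla4 1.45-fold and Cd8a 1.26-fold. The edgeR adjusted p-values of these genes lay between 0.00015 for Ctla4 and 0.0046 for Prf1 and for Il7r. Ifng rose from 64.4 ± 4.83 to 83.3 ± 4.91 CPM (adjusted p = 0.027). That call was lost on leaving out any of the 6 libraries compared (0.051 to 0.13), and in limma on log2(CPM + 1) and log2(CPM + 0.1) (0.082 and 0.21). Il10 rose from 49.0 ± 3.77 to 62.7 ± 2.83 CPM (adjusted p = 0.016). Its call was lost without replicates 2 or 3 of IL-12 or of IL-12 with TCM (0.064 to 0.088), and in limma on log2(CPM + 0.1) (0.19). Eomes and Tcf7 were not called (adjusted p = 0.052 and 0.093), and with the replicate block within the IL-2 groups they were called as lower (0.006 and 1.1e-05).

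Lipid synthesis genes were higher with TCM in IL-12. In the cholesterol list 24 of 25 genes rose (24, and 1 lower, adjusted over the list alone), such as Msmo1 from 129 ± 0.886 to 274 ± 12.4 CPM, Acat2 from 91.4 ± 2.59 to 188 ± 2.62 CPM and Cyp51 from 331 ± 10.8 to 522 ± 2.11 CPM. The median was 0.89 (camera adjusted p = 3.8e-23, and adjusted p = 0.048 with an estimated correlation), and no other list of this comparison kept its call with an estimated correlation. Of 16 fatty acid synthesis genes, 9 rose (9 adjusted over the list alone). Scd1 and Scd2, desaturases that make monounsaturated fatty acids, rose from 101 ± 4.86 to 248 ± 3.62 CPM and from 1260 ± 28.5 to 2350 ± 54.1 CPM. That list was called at adjusted p = 0.00062 (adjusted p = 0.065 with an estimated correlation).

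Genes of growth and division were lower with TCM in IL-12. In the DNA replication list 29 of 30 genes fell (29 adjusted over the list alone), with Mcm5 from 550 ± 13.7 to 330 ± 11.5 CPM and Mcm4 from 366 ± 18.6 to 223 ± 11.4 CPM (median -0.54, adjusted p = 2.2e-21, and adjusted p = 0.25 with an estimated correlation). In the mitosis list 21 of 28 fell (23 adjusted over the list alone), with Cdc20 and Kif20a 1.33- and 1.45-fold lower (adjusted p = 3.4e-11, and adjusted p = 0.34 with an estimated correlation). In the MYC list 22 of 27 fell (23 adjusted over the list alone). Mybbp1a and Fbl, nucleolar proteins of ribosome production, fell from 300 ± 14.8 to 183 ± 12.6 CPM and from 167 ± 6.91 to 110 ± 3.52 CPM (adjusted p of the list = 1.0e-10, and adjusted p = 0.33 with an estimated correlation). Of 15 histone genes, 4 fell (8 adjusted over the list alone; adjusted p = 0.0061, and adjusted p = 0.33 with an estimated correlation), and these near-identical genes can share reads and are uncertain.

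Some protein folding and mitochondrial genes were lower with TCM in IL-12. Of 15 heat shock genes, 7 fell (7 adjusted over the list alone), with Hspd1 1.33-fold and Hsp90aa1 1.22-fold lower (adjusted p of the list = 0.0079, and adjusted p = 0.41 with an estimated correlation). Of 24 unfolded protein response genes, 8 fell and 2 rose (8 and 3 adjusted over the list alone), with Dnajb9 from 14.4 ± 0.571 to 9.59 ± 0.790 CPM (adjusted p of the list = 0.0079, and adjusted p = 0.33 with an estimated correlation). Of 41 nuclear genes of oxidative phosphorylation, 14 fell and 1 rose (15 and 1 adjusted over the list alone), with Atp5b 1.22-fold lower (adjusted p of the list = 0.0083, and adjusted p = 0.69 with an estimated correlation). Of 13 mitochondrially encoded genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone), with mt-Atp6 from 44.9 ± 3.83 to 30.2 ± 1.59 CPM (adjusted p of the list = 0.028, and adjusted p = 0.69 with an estimated correlation). That call was lost without replicate 1 or 3 of IL-12 or replicate 3 of IL-12 with TCM (0.058, 0.054 and 0.073).

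Signalling genes moved in both directions with TCM in IL-12. Of 27 IL-2 and STAT5 targets, 14 rose and 2 fell (17 and 3 adjusted over the list alone), with Il4ra from 113 ± 7.79 to 213 ± 8.17 CPM and Socs1 from 46.6 ± 2.71 to 74.7 ± 10 CPM. This list was called at adjusted p = 0.00015 (adjusted p = 0.33 with an estimated correlation), and 0.13 without the genes shared with other lists. Of 50 interferon response genes, 19 rose and 4 fell (21 and 4 adjusted over the list alone), with Ddx58, Iigp1 and Slfn8 1.39-, 1.40- and 1.59-fold higher and Cxcl10 among the lower ones (adjusted p of the list = 0.0061, and adjusted p = 0.44 with an estimated correlation). Of 17 genes of the IL-12 and STAT4 axis, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with the IL-12 receptor gene Il12rb1 from 84.1 ± 3.37 to 140 ± 3.95 CPM and Runx3 1.42-fold higher. Its adjusted p of 0.045 (adjusted p = 0.31 with an estimated correlation) rose to between 0.053 and 0.074 without replicate 1 of IL-2, replicate 2 of IL-2 with TCM, replicate 3 of IL-12 or any replicate of IL-12 with TCM, and to 0.12 without shared genes. Of 21 TGF-beta response genes, 8 fell and 2 rose (8 and 2 adjusted over the list alone), with Ldlrad4 from 15.1 ± 0.869 to 6.41 ± 0.5 CPM (adjusted p of the list = 0.038, and adjusted p = 0.31 with an estimated correlation). Of 15 effector cytokine and chemokine genes, 7 fell and 3 rose (8 and 3 adjusted over the list alone), with Ltb from 613 ± 20.1 to 430 ± 23 CPM and Ccl4 from 7.15 ± 0.587 to 2.17 ± 0.527 CPM. The adjusted p of 0.044 (adjusted p = 0.34 with an estimated correlation) was 0.064 without replicate 3 of both IL-2 groups and 0.069 without shared genes. It was 0.05 to 0.076 without replicate 3 of IL-2, replicates 1 or 3 of IL-2 with TCM, replicates 2 or 3 of IL-12, or replicates 1 or 3 of IL-12 with TCM.

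Of 23 glycolysis genes, 3 rose with TCM in IL-12 (3 adjusted over the list alone), 2 of them Pfkfb3 from 28.1 ± 0.771 to 47.6 ± 1.42 CPM and Pfkfb4 from 4.75 ± 0.153 to 11.3 ± 0.523 CPM, which encode enzymes that switch glycolysis on. This list was called at adjusted p = 0.014 (adjusted p = 0.76 with an estimated correlation), and without replicate 3 of both IL-2 groups 21 of its genes were higher (8.4e-14, and adjusted p = 0.16 with an estimated correlation). These are the libraries with the high glycolysis genes, which share the estimate of spread. Of 26 hypoxia response genes, 3 rose (2 adjusted over the list alone; adjusted p = 0.062, without those libraries 20 higher and 2 lower, 8.3e-09, and adjusted p = 0.16 with an estimated correlation, with the block within the IL-2 groups 2.8e-08, and adjusted p = 0.22 with an estimated correlation). Among other cell types, 6 of 7 platelet genes fell and Itgb3 rose from 63.8 ± 4.41 to 89.5 ± 1.82 CPM (6 and 1 adjusted over the list alone), with Ppbp from 16.3 ± 1.49 to 5.82 ± 0.464 CPM (adjusted p of the list = 0.0046, and adjusted p = 0.33 with an estimated correlation). Cd4 rose from 0.584 ± 0.193 to 2.45 ± 0.276 CPM. Of 9 gamma-delta T cell genes, 3 fell (3 adjusted over the list alone). These were Tcrg-C1, Tcrg-C2 and Tcrg-C4, near-identical genes whose split of reads is uncertain (adjusted p of the list = 0.019, adjusted p = 0.41 with an estimated correlation, and 0.051 without replicate 1 of IL-12 with TCM).

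In this comparison edgeR called 4617 genes, 2353 higher and 2264 lower, of which 488 and 189 changed at least 2-fold. The count was 7133 with only the IL-12 groups in the fit and 7332 without replicate 3 of both IL-2 groups. It was 2931 without replicate 1 of IL-12 and 3067 without replicate 3 of IL-12 with TCM.

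The effects of TCM under IL-2 and under IL-12, which rest on separate libraries, were compared next. Of 1543 genes called in both, 1506 changed in the same direction, 730 higher and 776 lower, and 37 in opposite directions. Independent lists of these sizes would share 335 genes in direction. Both contrasts use the same estimate of spread per gene, which can raise this overlap. Across all genes that passed the filter on low counts, which are not independent replicates, the log2 fold changes had a Pearson r of 0.55 and a covariance of 0.112, and r was 0.12 without that filter and 0.37 without replicate 3 of IL-2 with TCM. Without replicate 3 of both IL-2 groups 2700 genes shared direction, and with the replicate block within the IL-2 groups 2970 did, while 883 did without replicate 1 of IL-2 and 964 without replicate 2.

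**Figure D2:**
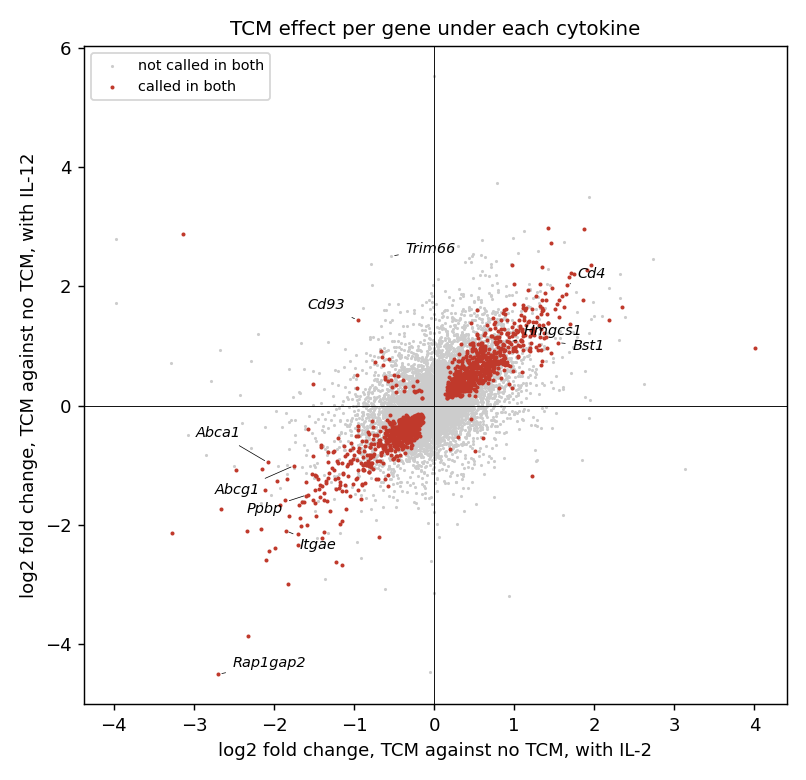
Log2 fold change with TCM in IL-2 (horizontal axis) against that in IL-12 (vertical axis), with one point per gene and genes called in both in red. Of 1543 genes called in both, 1506 lay in the quadrants of equal direction, among them Itgae and Rap1gap2, both lower.

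The difference between these effects was tested as an interaction of TCM and cytokine. Trim66 was at 1.37 ± 0.582 and 0.969 ± 0.297 CPM without and with TCM in IL-2 and rose 5.67-fold in IL-12 (log2 difference 3.04 ± 0.33 SE, n = 3 per group, edgeR adjusted p = 0.00068). Cd93, a surface receptor, was at 22.2 ± 1.28 and 11.4 ± 2.84 CPM in IL-2 and at 4.96 ± 0.379 and 13.3 ± 1.33 CPM in IL-12 (2.38 ± 0.21, adjusted p = 0.00026). Neb was at 28.2 ± 12.7 and 27.6 ± 7.12 CPM in IL-2, against its rise in IL-12 (1.87 ± 0.34, adjusted p = 0.014). Tmem154 fell further in IL-12 (-1.52 ± 0.14, adjusted p = 0.00026). Tbc1d4, which controls glucose transporter traffic, was at 79.8 ± 7.95 and 81.7 ± 9.18 CPM in IL-2 and 21.2 ± 2.12 and 9.09 ± 0.452 CPM in IL-12 (-1.25 ± 0.15, adjusted p = 0.001). Abca1 and Abcg1 fell further in IL-2, with log2 differences of 1.12 ± 0.12 and 0.74 ± 0.12 (adjusted p = 7.0e-04 and 0.01). For Prf1, Gzmb and Lag3 the difference was not called (adjusted p = 0.61, 0.18 and 0.2), and with the replicate block within the IL-2 groups it was (0.00073, 6.4e-05 and 1.2e-08). Over all alternatives these values ran from 1.8e-05 to 0.89, from 4.5e-14 to 0.35 and from 1.4e-17 to 0.38.

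Among gene lists, the effect of TCM in IL-12 was above that in IL-2 for cholesterol synthesis (3 of 25 genes, 7 adjusted over the list alone), fatty acid synthesis (2 of 16, 5 adjusted over the list alone), interferon response (6 of 50, and 12 higher and 3 lower adjusted over the list alone) and IL-2 and STAT5 target genes (1 of 27, and 7 higher and 2 lower adjusted over the list alone). Their adjusted p-values were 0.00026, 0.00011, 0.00032 and 0.0023, and with an estimated correlation adjusted p = 0.53, 0.065, 0.53 and 0.53. It was below that in IL-2 for the MYC list (1 of 27, 5 adjusted over the list alone) and the mitochondrially encoded genes (1 of 13, 4 adjusted over the list alone), at 3.2e-06 and 0.00011 (adjusted p = 0.53 for both with an estimated correlation). The DNA replication and oxidative phosphorylation lists were called as lower too, at 0.00011 and 0.0021 (adjusted p = 0.62 and 0.64 with an estimated correlation), with no member called. The oxidative phosphorylation call was lost without replicate 3 of IL-2 (0.12), and that of the STAT5 targets without genes shared with other lists (0.4). Without replicate 3 of both IL-2 groups, 17 STAT5 targets were higher and 2 lower, 10 cholesterol synthesis genes higher and 1 lower, 8 fatty acid synthesis genes higher, and 14 interferon response genes higher and 8 lower. In that fit 14 DNA replication, 8 mitochondrially encoded and 5 oxidative phosphorylation genes were lower, and 10 MYC list genes lower and 1 higher (adjusted p = 0.23 to 0.68 for these lists with an estimated correlation). Glycolysis and hypoxia response genes were not called (adjusted p = 0.15 and 0.14), and with the block within the IL-2 groups they were called with a higher effect in IL-12 (6e-11 and 5.3e-07, and adjusted p = 0.42 and 0.37 with an estimated correlation). Of all genes, 251 were called for the difference, 189 higher and 62 lower, of which 54 and 10 differed at least 2-fold. The count was 550 in DESeq2, 779 without the filter on low counts, 2105 without replicate 3 of both IL-2 groups and 1668 with the block within the IL-2 groups. It was 1164 without replicate 3 of IL-2 with TCM, 148 without replicate 2 of IL-2, and 149 and 142 without replicates 1 and 2 of IL-2 with TCM. Without replicates 1, 2 and 3 of IL-12 it was 108, 114 and 121, and without those of IL-12 with TCM 114, 105 and 116.

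The comparison of IL-12 with IL-2 in the absence of TCM asked how gene levels differed between the cytokines. No group was without a cytokine, so effects of IL-12 and of any absence of IL-2 cannot be told apart. P2rx3, an ATP-gated channel, was at 238 ± 1.54 CPM with IL-12 against 1.10 ± 0.399 CPM with IL-2 (n = 3; 215-fold). The cytokine genes Il10 (ENSMUSG00000016529), Csf1 and Ifng (ENSMUSG00000055170) were at 49.0 ± 3.77, 155 ± 8.10 and 64.4 ± 4.83 CPM against 0.789 ± 0.326, 3.66 ± 0.797 and 1.53 ± 0.603 CPM (62-, 42- and 41.5-fold). Furin, a protease that activates precursor proteins, was at 1940 ± 99.6 against 116 ± 8.73 CPM, and the IL-18 receptor gene Il18r1 at 907 ± 20.4 against 50.9 ± 1.2 CPM. Tbx21, which encodes T-bet, Il2ra and Pdcd1, which encodes PD-1, were 1.74-, 2.73- and 2.54-fold higher. Itgae was 10.8-fold lower with IL-12 (249 ± 14.2 to 23.2 ± 0.852 CPM), and Gzmb (2.26-fold), Tcf7 (2.14-fold), Eomes (2.15-fold) and Ccr7 (1.68-fold) were lower as well. Adjusted p-values from edgeR for these genes lay between 2.5e-13 for Furin and 0.00042 for Gzmb. Prf1, Lag3 and Mki67 were not called (adjusted p = 0.12, 0.89 and 0.7), and with the block within the IL-2 groups Prf1 was called as higher (1.8e-07).

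In the IL-12 and STAT4 list 10 of 17 genes were higher and 4 lower (10 and 4 adjusted over the list alone; median 0.80, camera adjusted p = 0.0018, and adjusted p = 0.049 with an estimated correlation). The lower ones included Stat4 itself, at 80.9 ± 1.87 against 98.2 ± 1.78 CPM. Of 15 effector cytokine and chemokine genes, 11 were higher and 3 lower (11 and 4 adjusted over the list alone; adjusted p = 6.0e-04, and adjusted p = 0.12 with an estimated correlation). Of 25 immediate early genes, 17 were higher and 3 lower (18 and 3 adjusted over the list alone). Fosl2 and Jun, subunits of the factor AP-1, were at 119 ± 3.71 and 252 ± 1.05 CPM against 12.8 ± 2.74 and 27.8 ± 3.19 CPM (adjusted p of the list = 9.5e-05, and adjusted p = 0.046 with an estimated correlation). Of 25 cholesterol synthesis genes, 23 were higher (24 adjusted over the list alone), such as Idi1 2.28-fold and Cyp51 1.94-fold (adjusted p of the list = 7.4e-14, and adjusted p = 0.049 with an estimated correlation). Of 16 fatty acid synthesis genes, 13 were higher and 1 lower (13 and 1 adjusted over the list alone), such as Fads2 2.44-fold and Elovl5 2.10-fold (adjusted p of the list = 7.2e-06, and adjusted p = 0.031 with an estimated correlation).

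Genes of DNA replication, mitosis, MYC activity, oxidative phosphorylation and stress responses were called higher with IL-12 than with IL-2, in shares that differed between lists. In the DNA replication list 25 of 30 were higher (26 adjusted over the list alone), with Pcna at 1030 ± 27.9 against 449 ± 35.6 CPM. The adjusted p of the list was 2.7e-08 (adjusted p = 0.3 with an estimated correlation). In the mitosis list 11 of 28 were higher (11 adjusted over the list alone; adjusted p = 0.0038, and adjusted p = 0.63 with an estimated correlation). In the MYC list 18 of 27 were higher (20, and 1 lower, adjusted over the list alone), with Myc 1.62-fold and Nop56 1.61-fold higher (adjusted p of the list = 3.1e-05, and adjusted p = 0.38 with an estimated correlation). In the oxidative phosphorylation list 31 of 41 were higher (32 adjusted over the list alone), with Cox5a 1.71-fold and Cycs 2.30-fold higher (adjusted p of the list = 5.1e-07, and adjusted p = 0.3 with an estimated correlation). Of 24 unfolded protein response genes, 16 were higher (16 adjusted over the list alone), with the stress sensors Ern1 and Atf6 2.79- and 1.79-fold higher (adjusted p of the list = 9.5e-05, and adjusted p = 0.12 with an estimated correlation). Of 15 heat shock genes, 9 were higher (10, and 1 lower, adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.31 with an estimated correlation). Of 24 NRF2 targets, 13 were higher and 3 lower (13 and 3 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.15 with an estimated correlation).

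Other groups were lower with IL-12. Of 50 interferon response genes, 30 were lower and 11 higher (31 and 11 adjusted over the list alone). Irf7 was at 17.4 ± 1.19 against 49.0 ± 2.14 CPM, and Iigp1 and Gbp6 were 2.60- and 3.54-fold lower, Gbp6 and Gbp10 belonging to a family of near-identical genes that can share reads. The adjusted p of the list was 0.0039 (adjusted p = 0.41 with an estimated correlation). Of 22 naive and memory genes, 13 were lower and 4 higher (14 and 4 adjusted over the list alone), with Bcl2, a survival gene, at 139 ± 3.62 against 345 ± 7.61 CPM and Dapl1 7.18-fold lower. That list was called at adjusted p = 0.0067 (adjusted p = 0.61 with an estimated correlation), and not without genes shared with other lists (0.15). Of 10 type 2 genes, 7 were lower and 1 higher (7 and 1 adjusted over the list alone). Gata3, the regulator of type 2 T cells, was at 18.5 ± 0.527 against 57.1 ± 1.5 CPM, and Il4ra was 2.58-fold lower. The higher one was Il1rl1, the IL-33 receptor gene, at 65.1 ± 1.73 against 5.39 ± 1.24 CPM, named after its values were seen. The adjusted p of the list was 0.0045 (adjusted p = 0.08 with an estimated correlation), and 0.39 without shared genes.

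Transcripts of some other cell types were lower with IL-12 too. Of 7 MHC class II genes, 6 were lower (7 adjusted over the list alone), with Cd74 at 15.4 ± 1.13 against 35.2 ± 4.28 CPM (adjusted p of the list = 9.5e-05, and adjusted p = 0.046 with an estimated correlation). All 7 platelet genes were lower (7 adjusted over the list alone), with Itgb3 at 63.8 ± 4.41 against 209 ± 18.5 CPM (adjusted p of the list = 0.00018, and adjusted p = 0.15 with an estimated correlation). Of 9 B cell genes, 5 were lower and 1 higher (6 and 1 adjusted over the list alone). Ighm was at 84.4 ± 2.30 against 647 ± 179 CPM and Cd79b at 4.92 ± 0.340 against 15.8 ± 1.45 CPM, whereas the antibody light chain gene Igkc, named after its values were seen, was at 7.36 ± 0.398 against 3.09 ± 0.351 CPM. The B cell call (adjusted p = 0.016, and adjusted p = 0.29 with an estimated correlation) was lost without replicate 1 of IL-12 (0.052). All 5 epithelial and melanoma genes were lower (5 adjusted over the list alone) at levels such as 0.581 ± 0.020 against 1.92 ± 0.417 CPM for Epcam (adjusted p of the list = 0.034, and adjusted p = 0.15 with an estimated correlation), and that call was lost with upper-quartile scaling (0.063). Gamma-delta T cell genes (of 9, 6 higher and 1 lower, 6 and 3 adjusted over the list alone, adjusted p = 0.084) and NK cell genes (of 10, 3 higher and 3 lower, 4 and 3 adjusted over the list alone, adjusted p = 0.57) were not called.

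The glycolysis list was not called (3 of 23 genes higher and 3 lower, 3 and 3 adjusted over the list alone, adjusted p = 0.85), and without replicate 3 of both IL-2 groups it was called as higher (14 and 3, adjusted p = 7.7e-05, and adjusted p = 0.31 with an estimated correlation), and 21 mitosis genes were higher instead of 11 (adjusted p = 0.27 with an estimated correlation). For IL-12 against IL-2 without TCM edgeR called 7171 genes, 3511 higher and 3660 lower, of which 582 and 1164 differed at least 2-fold. With upper-quartile scaling, which moved the median of all genes by -0.08 on the log2 scale, the split was 2593 higher and 4532 lower.

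**Figure D3:**
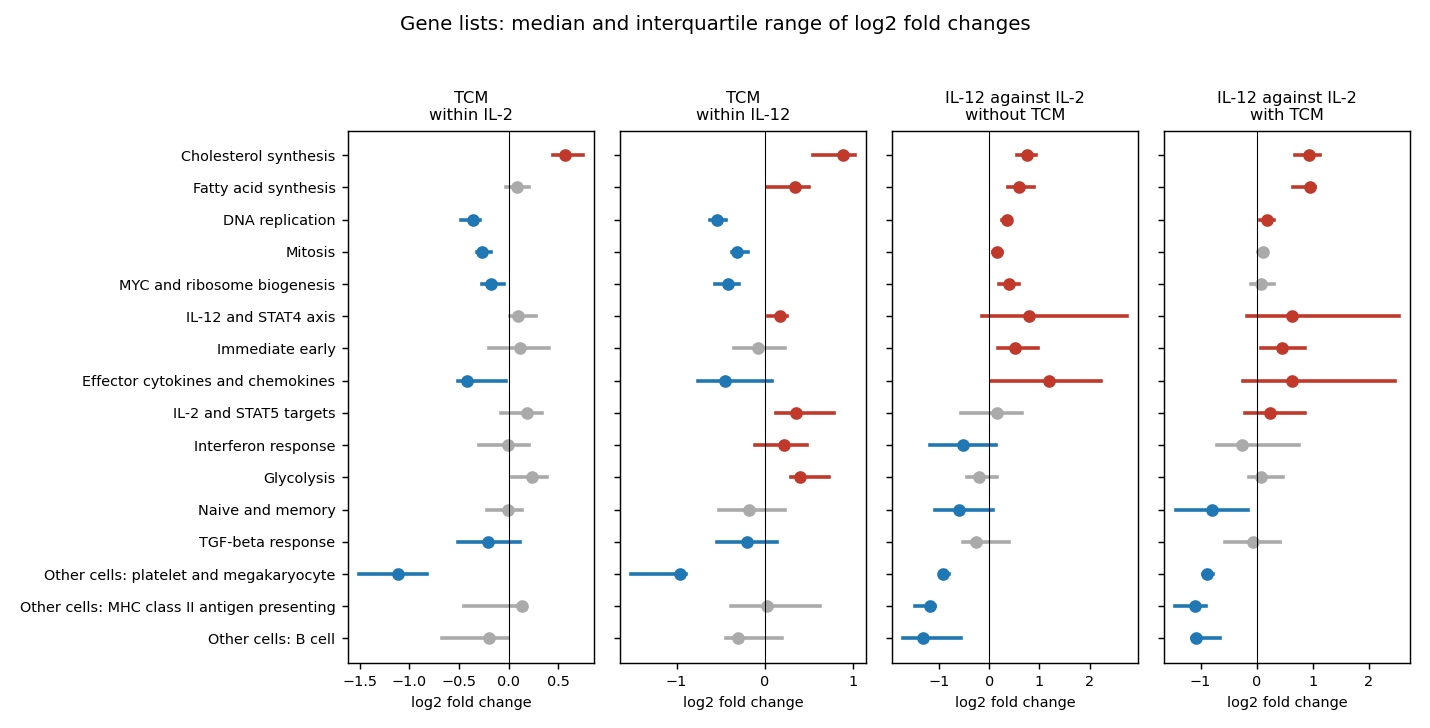
Median and interquartile range of the log2 fold change over the genes of 16 lists in 4 contrasts, with lists called higher in red, called lower in blue and not called in grey. Cholesterol synthesis was higher in all 4 contrasts, with medians of 0.57, 0.89, 0.75 and 0.94, and DNA replication was lower with TCM and higher with IL-12. With an estimated correlation the cholesterol synthesis calls were kept in all 4 and the DNA replication calls in none (adjusted p = 0.22, 0.25, 0.3 and 0.54 with an estimated correlation).

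The same comparison in the presence of TCM gave P2rx3 at 201 ± 7.07 against 0.672 ± 0.3 CPM (n = 3; 307-fold), Il10 at 62.7 ± 2.83 against 0.556 ± 0.0752 CPM (113-fold), Csf1 at 276 ± 12.5 against 3.09 ± 1.55 CPM (90.7-fold) and Ifng at 83.3 ± 4.91 against 1.72 ± 0.310 CPM (48.7-fold). Fam20a, a secretory pathway pseudokinase, was at 59.8 ± 4.07 against 0.486 ± 0.273 CPM. Furin and Il18r1 were 19.8- and 16.6-fold higher. Prf1 and Lag3 were higher with IL-12 when TCM was present, at 102 ± 11.5 against 41.9 ± 25.8 CPM and 377 ± 26.4 against 188 ± 77.1 CPM. Itgae was 12.7-fold lower (68.9 ± 6.39 to 5.43 ± 1.02 CPM), Wnt10b, a secreted signalling protein, 15.5-fold, Tspan32 11.7-fold, Tcf7 3.11-fold and Tox 3.72-fold. The edgeR adjusted p-values lay between 1.3e-13 for Furin and 0.0075 for Prf1, and Gzmb was not called (1070 ± 84.8 against 1370 ± 446 CPM, adjusted p = 0.18, and 0.0052 with the replicate block within the IL-2 groups, with alternatives from 2.8e-06 to 0.74).

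With TCM present, 24 of 25 cholesterol synthesis genes were higher with IL-12 (24 adjusted over the list alone), with Acat2 at 188 ± 2.62 against 71.9 ± 2.64 CPM (adjusted p of the list = 5.5e-19, and adjusted p = 0.042 with an estimated correlation). Of 16 fatty acid synthesis genes, 14 were higher and 1 lower (14 and 1 adjusted over the list alone), with Fads2 3.30-fold and Acly 1.72-fold higher (adjusted p of the list = 6.8e-09, and adjusted p = 0.0065 with an estimated correlation). In the IL-12 and STAT4 list 11 of 17 were higher and 3 lower (11 and 5 adjusted over the list alone; adjusted p = 0.001, and adjusted p = 0.044 with an estimated correlation). Of 27 IL-2 and STAT5 targets, 11 were higher and 6 lower (11 and 6 adjusted over the list alone), with Pim1, a survival kinase, at 595 ± 30.3 against 154 ± 2.83 CPM and Socs3 2.75-fold higher. That call (adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation) was lost without replicate 1 or 2 of IL-2 with TCM (0.07 and 0.052). Of 15 effector cytokine and chemokine genes, 9 were higher and 3 lower (10 and 3 adjusted over the list alone; adjusted p = 0.011, adjusted p = 0.24 with an estimated correlation, and 0.097 without shared genes). Of 25 immediate early genes, 13 were higher and 3 lower (15 and 3 adjusted over the list alone), with Fos 12.3-fold and Jun 11-fold higher (adjusted p of the list = 0.011, and adjusted p = 0.17 with an estimated correlation).

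Of 30 DNA replication genes, 15 were higher with IL-12 when TCM was present (16 adjusted over the list alone), and of 41 oxidative phosphorylation genes 17 were (19 adjusted over the list alone), at adjusted p = 0.001 and 0.0015 (adjusted p = 0.54 for both with an estimated correlation). Of 24 unfolded protein response genes, 12 were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 0.0028, and adjusted p = 0.24 with an estimated correlation). Of 15 heat shock genes, 7 were higher (7 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.51 with an estimated correlation). Of 24 NRF2 targets, 12 were higher and 4 lower (12 and 4 adjusted over the list alone). Fth1, a ferritin chain that stores iron, was at 909 ± 17.7 against 306 ± 26.1 CPM (adjusted p of the list = 0.019, and adjusted p = 0.24 with an estimated correlation). Of 37 ATF4 targets, 12 were higher and 3 lower (12 and 3 adjusted over the list alone), with the amino acid transporter gene Slc38a2 1.70-fold higher, and 22 and 4 without replicate 3 of both IL-2 groups (adjusted p = 0.26 with an estimated correlation). That call (adjusted p = 0.041, and adjusted p = 0.62 with an estimated correlation) was lost with the replicate number as a block over all libraries (0.068) or within the IL-2 groups (0.053). It was also lost without replicate 3 of IL-2, replicates 1 or 2 of IL-2 with TCM, replicate 2 of IL-12 or replicate 1 of IL-12 with TCM (0.054 to 0.13).

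Of 22 naive and memory genes, 14 were lower and 4 higher with IL-12 when TCM was present (15 and 5 adjusted over the list alone; adjusted p = 0.0016, adjusted p = 0.55 with an estimated correlation, and 0.1 without shared genes). Of other cell types, all 7 platelet genes were lower (7 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.24 with an estimated correlation), as were 5 of 7 MHC class II genes (5 adjusted over the list alone; adjusted p = 0.0067, and adjusted p = 0.14 with an estimated correlation). Of 9 B cell genes, 5 were lower and 1 higher (6 and 1 adjusted over the list alone), with Ighm at 62.1 ± 2.31 against 563 ± 240 CPM. That call (adjusted p = 0.03, and adjusted p = 0.35 with an estimated correlation) was lost with upper-quartile scaling (0.068). It was also lost without replicates 1 or 3 of IL-2, 1 or 2 of IL-2 with TCM, 1 or 3 of IL-12, or 2 or 3 of IL-12 with TCM (0.052 to 0.085).

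With TCM present the glycolysis list was not called either (3 of 23 genes higher and 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.23), and without replicate 3 of both IL-2 groups it was called as higher (20 and 2, adjusted p = 3.5e-12, and adjusted p = 0.23 with an estimated correlation), as it was with the block within the IL-2 groups (0.0016, and adjusted p = 0.51 with an estimated correlation). For IL-12 against IL-2 with TCM edgeR called 6192 genes, 3106 higher and 3086 lower, of which 742 and 921 differed at least 2-fold, and with upper-quartile scaling the split was 2331 higher and 3971 lower. Of 4705 genes called for the cytokine both without and with TCM, 4678 had the same direction, 2335 higher and 2343 lower, and 27 the opposite, where independent lists would share 1396. The shared estimate of spread per gene can raise this overlap too. Across genes the log2 fold changes of these contrasts, which share no libraries, had a Pearson r of 0.86 and a covariance of 0.581, and r was 0.32 without the filter on low counts.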

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

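The results below were marked for a closer look because the effect of TCM differed between IL-12 and IL-2 and this difference was itself tested as an interaction term. Of the tests in this part, the test of a lower sterol level under both cytokines and those on regrouped samples were written before their results, and all others after results were seen. In all, 251 genes were called for the difference. The log2 differences were 3.04 for Trim66 (adjusted p = 0.00068), 2.38 for Cd93 (0.00026), 2.22 for Cxcr2 (0.0087), 2.20 for Serpinb5 (0.043), 1.88 for Fam20a (0.012) and 1.87 for Neb (0.014). On the other side they were -1.81 for Rap1gap2 (0.016), -1.55 for Arhgap29 (0.021), -1.52 for Tmem154 (0.00026), -1.52 for Gucy2e (0.01), -1.28 for Wnt10b (0.012) and -1.25 for Tbc1d4 (0.001). Cxcr2 lost its call without replicate 2 of IL-2 (0.1), Rap1gap2 without replicates 1 or 2 of IL-12 with TCM (0.05 and 0.059) and in limma on log2(CPM + 5) (0.27), and Gucy2e in limma on log2(CPM + 5) (0.66). Serpinb5 lost it without any of 10 libraries (0.055 to 0.23), all but replicate 1 of IL-2 and replicate 3 of IL-2 with TCM, and in limma on log2(CPM + 0.1) (0.066). Arhgap29 lost it without any of 8 libraries (0.057 to 0.088), namely replicates 1 and 2 of IL-2 with TCM and the 6 IL-12 libraries.

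Regrouping the samples asked whether other groupings give as many calls. For TCM within IL-2, TCM within IL-12, and IL-12 against IL-2 without and with TCM, 1 of 10 splits of 3 against 3 gave as many calls, namely the real one, with 587, 7133, 7085 and 5241 calls and 0 as the highest other count. That is too few splits for a share under 0.05. For the difference of effects, 3 of 100 randomly drawn splits gave at least the 251 calls of the real one, the real one included, and the highest other count was 1554. The share lay under 0.05 in these 100, but not in the 30 drawn at first, of which 2 gave as many, the real one included. The number was raised after that count was seen, so the 100 do not exclude chance. Drawn splits also leave the real difference in the spread, which can lower their calls. The 2 other splits with as many calls, 1554 and 1079, set replicate 3 of both IL-2 groups apart from replicates 1 and 2, which points to a structure of the samples. The difference had 2105 calls without these libraries and 1668 with the block within the IL-2 groups, for which no splits were run.

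The first pattern weighed is that replicate 3 of IL-2 and of IL-2 with TCM stood apart. An IL-12 library mixed in or exchanged was excluded as a candidate explanation, since the median share of the IL-12 level was 0.0077 at most over 43 and 67 genes. Values argued against cells of a type on 8 of the 9 other-cell lists with at least 5 tested genes, since the upper quartile of the shifts of their genes was 0.14 at most in the lower of the 2 libraries. The neutrophil, dendritic cell, erythroid and liver lists had fewer tested genes and were not examined. The baseline with TCM included replicate 2, with Fn1 at 24.5 CPM, and for the stromal list the upper quartile in IL-2 without TCM was 0.15. Epithelial or melanoma cells stay open, with an upper quartile of 0.93 over 5 genes that moved both ways. Cdh1, named after its values were seen, was at 18.9 against 4.85 and 4.39 CPM, and at 7.74 against 0.775 and 0.369 CPM with TCM. A low-oxygen type response of the culture stays open, since the 24 hypoxia genes outside the glycolysis list, which shifted by medians of 1.17 and 1.40, belong to what set these libraries apart and cannot count for the cause (the glycolysis list shifted by 1.18 and 1.25, and no list besides these by more than 0.16 in both). No biological explanation tied to a group was tested, since both IL-2 groups share the shift.

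The next pattern is the fall of platelet and megakaryocyte genes with TCM under both cytokines. Less platelet RNA carried along with the cells stays open for the list, whose 7 genes had medians of -1.11 under IL-2 and -0.96 under IL-12, though it would not make Itgb3 rise (0.49 under IL-12). For the other members it stays open too, since 8 platelet genes outside the list had medians of -1.27 under IL-2 and -1.31 under IL-12, with Gp1ba at 0.44 under IL-12 (adjusted p = 0.065) and the other 7 below 0 under both (Clec1b not called, 0.057 and 0.054), while the 6 members without Itgb3 fell by unequal amounts, from -0.78 to -1.70 under IL-2 and from -0.85 to -2.15 under IL-12. The choice among TMM, upper-quartile and DESeq2 scaling was excluded, since medians moved by at most 0.024, while a shift common to these scalings was not tested.

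The last pattern is the rise of cholesterol synthesis genes beside the fall of Abca1 and Abcg1 with TCM. The biological explanation weighed was a lower sterol level of the cells under both cytokines. It predicted a fall of 5 other genes taken as targets of the sterol receptor LXR (Mylip, Smpdl3a, Arl4c, Nr1h3 and Lpcat3). That prediction failed under IL-12, where their median was 0.31, with 2 called higher and 0 lower in edgeR. These 5 genes alone cannot exclude the explanation, and whether they answer to LXR in mouse T cells was not tested. Nr1h3 was at 0.704 and 0.873 CPM in IL-12 without and with TCM (0.31 ± 0.34 SE). Abca1 and Abcg1 themselves fell there (log2 fold changes -0.95 and -1). Under IL-2 alone a lower sterol level stays open too, since the median was -0.22 and depends on the choice of genes. In edgeR, Mylip (-1.01, adjusted p = 8.2e-05) and Arl4c (-0.52, adjusted p = 0.00011) were lower and Smpdl3a higher (0.50, adjusted p = 0.00023). Lpcat3 (-0.22, adjusted p = 0.063) and Nr1h3 (-0.1, adjusted p = 0.88) were not called. The choice among these scalings was excluded as a possible explanation here too, with a shift of at most 0.024.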

How the results depend on the processing

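The alternatives in this part were planned, except leaving out replicate 3 of both IL-2 groups and the block within the IL-2 groups, each also with an estimated correlation, which were chosen after results were seen. Of 368 values of named genes, 298 kept their side of the threshold under every alternative, 20 called ones lost it on leaving out some library, 23 in another alternative, and 44 not called were called in some. Direction was compared only where either fit called the gene, and there 0 turned. Of 70 called lists, 10 kept the call with an estimated correlation. For TCM within IL-2 (2313 genes) the count was 587 with only the 2 groups compared, 3936 without replicate 3 of both IL-2 groups, 341 with an absolute log2 fold change of at least 1, and 1292 to 2938 with 1 library left out. For TCM within IL-12 (4617) it was 7133, 7332, 677 and 2931 to 5697. For IL-12 against IL-2 the size limit left 1746 of 7171 genes without TCM and 1663 of 6192 with TCM, and leaving out libraries gave 5595 to 8153 and 4910 to 6747. For the difference of effects (251) it was 779 with no filter on low counts, 550 in DESeq2, 2105 without replicate 3 of both IL-2 groups, 64 with the size limit and 105 to 1164 with 1 library left out. Genes moved alike by TCM under both cytokines (1506) were 2700 without replicate 3 of both IL-2 groups and 883 to 1986 with 1 library left out. Across genes, r was 0.12 instead of 0.55 for the effects of TCM and 0.32 instead of 0.86 for those of the cytokine with no filter on low counts. The size limit lowers counts by its construction, and for the other moves the cause was not tested. DESeq2 gave no adjusted p for 1262 genes in TCM within IL-2 and 3417 in the difference. Limits from depth were not tested apart.

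With the replicate number as a block within the IL-2 groups, where every same-number correlation was above 0.1 but only replicate 3 was told apart by its number, 4442 genes were called for TCM within IL-2, 1668 for the difference and 2970 moved alike. Beyond the calls named in the report it brought in lists (ATF4 0.029 and NRF2 0.046 in TCM within IL-12, mitochondrially encoded and gamma-delta T cell genes 0.041 each in IL-12 against IL-2 without TCM, costimulation 0.039 with TCM, NF-kB targets 0.03 and gamma-delta T cell genes 0.031 in the difference), none of them kept with that block and an estimated correlation (adjusted p = 0.35 to 0.67 with an estimated correlation). For TCM within IL-12 it brought in Slc2a1 7.6e-05, Tbx21 0.00014, Havcr2 0.0015, Pdcd1 0.002, Il12rb2 0.0025, Tox 0.0098 and Il18r1 0.01, with Tox lower and the others higher. In the difference it brought in Il12rb1 4.8e-07, Tcf7 0.00025, Il12rb2 3e-04, Havcr2 0.00087, Slc2a1 0.0019, Il7r 0.0028, Il2ra 0.0033, Stat4 0.0076, Tox 0.0077 and Eomes 0.042, with Tcf7, Il12rb2, Stat4, Tox and Eomes lower and the others higher. The block changed no other call printed here of lists and of genes under the naming rule. Genes outside that rule were not checked, and the cause was not tested. A block over all libraries gave 2722, 4949, 7454, 6542 and 330 calls. That block also brought in Tox 0.049 for TCM within IL-12 and Prf1 0.048 for IL-12 against IL-2 without TCM.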

Other observations

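All genes and tests in this part were chosen after their values were seen. Several genes of killing and inhibition moved without their lists being called. Serpinb6b, an inhibitor of granzyme-type proteases, rose with TCM from 58.1 ± 8.68 to 127 ± 29.4 CPM in IL-2 (n = 3, edgeR adjusted p = 2e-04) and from 32 ± 0.285 to 96.8 ± 2.57 CPM in IL-12 (adjusted p = 8.8e-06). Fasl, a death ligand, rose with TCM in both (adjusted p = 0.01 and 0.00031), and Nkg7, a granule protein, was higher with IL-12 (564 against 273 CPM, adjusted p = 1.6e-07). Gzmc fell with TCM in IL-2 (73.5 to 40.5 CPM, adjusted p = 0.00069). The cytotoxic granule list of 19 genes had 3 higher and 3 lower for TCM in IL-2, 5 and 6 for TCM in IL-12, 7 and 5 for IL-12 without TCM and 8 and 4 with TCM (adjusted p = 0.82, 0.62, 0.31 and 0.23). The inhibitory receptor genes Btla and Cd200 were at 98.9 and 55.6 CPM with IL-12 against 14 and 9.53 CPM with IL-2, log2 2.82 and 2.54, while their list of 27 genes had 7 higher and 11 lower (adjusted p = 0.74).

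The fatty acid oxidation and lipid handling list of 26 genes was not called, with 6 higher and 4 lower for TCM in IL-2, 8 and 6 for TCM in IL-12, 4 and 7 for IL-12 without TCM and 6 and 9 with TCM (adjusted p = 0.43, 0.62, 0.62 and 0.46). Acadl, an acyl-CoA dehydrogenase, was at 110, 126, 242 and 359 CPM in IL-2, IL-2 with TCM, IL-12 and IL-12 with TCM, with a TCM effect larger in IL-12 (log2 difference 0.38, adjusted p = 0.036). Cpt1a, which takes fatty acids into mitochondria, rose with TCM in IL-2 (130 to 173 CPM, adjusted p = 0.0014) and was lower with IL-12 (87.4 CPM, log2 -0.57). Entpd1, an ectonucleotidase, rose with TCM in IL-12 from 29.1 to 80.2 CPM (adjusted p = 0.00068), and the difference from IL-2 was not called (adjusted p = 0.093).

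Of genes at 2 CPM or more in the library in question, 7 in replicate 2 of IL-2 with TCM were at least 4 times as high as in any of the 11 other libraries: Fn1 24.5 against at most 1.01 CPM, Col1a1 11 against 1.55, Tpm2 3.43 against 0.518, Col1a2 3.39 against 0.599, Mmp2 3.36 against 0.533, Fap 2.91 against 0.161 and Igfbp7 2.62 against 0.291. In replicate 3 of IL-2 with TCM these were C3 (6.58 against 1.38), Fam71f2 (6.58 against 1.44) and Myh7b (5.34 against 0.71), and in replicate 1 of IL-12 it was Gm18194 (33.6 against 2.29).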
